A study of Caenorhabditis elegans with 4 samples.

How the data were processed

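Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Caenorhabditis elegans hermaphrodites at the fourth larval stage (L4), grown at 20 °C. Per the labels, the worms carried a lin-13 transgene with EGFP and FLAG tags, made by bombardment together with unc-119 as the rescue marker. LIN-13 is a nuclear zinc-finger protein of the class B synthetic Multivulva group, which opposes vulval cell fates. Per the labels' protocols, chromatin was crosslinked with formaldehyde, sheared by sonication and precipitated with affinity-purified antibodies against GFP, and part of each extract was set aside as input DNA. The series has 4 samples, of which 2 are LIN-13 ChIP samples and 2 are input DNA samples. Groups were taken from the titles. The description fields do not match the titles, since those of the ChIP samples read input DNA and those of the input samples name both the antibody and input DNA.

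Peak lists were used for ChIP replicate 1, for ChIP replicate 2 and for a list named as combined. Per the file headers, the authors called the peaks with PeakSeq, a caller that compares ChIP reads with input reads, on genome build WormBase WS180. The PeakSeq version, the aligner, the filters and the way in which the combined list was made are not given in the sources used here. The only measurement deposited with each peak is a q-value on a linear scale, given as the score and repeated as an attribute. These q-values are the authors' own and were used to describe and rank peaks within a list. They were converted here to −log10 q, and a larger value is called a stronger peak. Where −log10 q is set side by side between lists, for overlapping peaks, the values also carry the unknown depths of the lists. No read counts, signal or input values were used, so the sequencing depth of each library is unknown, and no fold enrichment or input background can be given. The deposited peaks end at a largest q-value of 0.000238 in the combined list, 0.000148 in replicate 1 and 0.000102 in replicate 2, so the lists differ in how far they reach.

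Overlaps, chromosome shares and rank correlations were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Peaks were counted as shared at an overlap of at least 1 bp, and the counts were checked against bedtools 2.31.1, with the same result for all list pairs. The overlap expected by chance came from 1000 random placements of the peaks of one list on their own chromosomes with widths kept, in a one-sided permutation test whose smallest p is 0.000999. Chromosome lengths of build WS180 were not used. The length of each of the 6 nuclear chromosomes was taken as the farthest peak end in any list, which is a lower bound. Chromosome shares were tested with a two-sided exact binomial test and Benjamini-Hochberg adjustment over the 6 chromosomes of a list. Chromosome arms were defined before the data were examined as the outer 25% at each end, and the centre as the middle 50%. Intervals on shares are 95% Wilson intervals. They treat peaks as independent and cover counting error only. Peaks cluster, so the shares of the 6 chromosomes and of the arms in the combined list, and the arms within each chromosome in every list, were also tested with 1 Mb bins as units, in two-sided permutation tests with 100000 resamples. The chromosome shares of the replicate lists were tested on peaks only. Correlations of −log10 q were taken across overlapping peak pairs, with 1 pair for each replicate 2 peak, and peaks are not independent replicates. The chance that a combined-list peak is also in a replicate list was compared between chromosomes with a Mantel-Haenszel odds ratio over 10 strata of the combined list ranked by q-value, with a one-sided permutation test within strata. The 7 permutation tests on bins of the combined list were adjusted together by the Benjamini-Hochberg method, and those of arms within chromosomes over the 6 chromosomes of a list.

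The calculations were checked on simulated data, in which shared peaks were exact copies and peaks were drawn independently. These checks cover the calculations only, not how the tests behave on clustered peaks. For the replicate comparison, 1309 simulated peaks made with 59.5% shared gave 60.0%. For the comparison of chromosomes within strata, 2769 simulated peaks made with an odds ratio of 0.25 gave 0.252.

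The reference table at hand describes assembly WBcel235, whereas the peaks are on WS180. Peaks were therefore not joined to genes. The planned results on gene 5′ ends, gene lists, the lin-13 and unc-119 loci and sequence motifs were not analysed here. The transgene adds copies of lin-13 and unc-119, so a peak at either locus could come from copy number. Such peaks were not identified or set aside. The rule fixed for naming genes began from the 20 combined-list peaks with the smallest q-values that overlap a peak in both replicates and took the protein-coding genes with a 5′ end near their centres, then members of gene lists, lin-13 and unc-119. Only its first step was applied, so the text names those regions and not their genes. Regions outside that rule were named after their values were seen. Alternatives fixed at the same time as the arms were a stricter overlap, centres within 200 bp, the stronger 50% of each list, equal list lengths, each replicate list alone and the combined peaks found in both replicates. Alternatives without chromosome I or III, with 1 Mb bins, and all alternatives for chromosomes I and III were added after the data were seen.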

Results

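LIN-13::EGFP binding was mapped by ChIP-seq in L4 hermaphrodites, with 2 ChIP samples and 2 input DNA samples. The labels do not say whether the replicates came from separate cultures, and the tests below take peaks, peak pairs or 1 Mb bins as units, so they say nothing of the spread between cultures. The replicate 1 list held 1309 peaks, the replicate 2 list 734 and the combined list 2769. Read depth is unknown for all 3 lists. Peaks had similar widths, with medians of 483 bp in replicate 1, 482 bp in replicate 2 and 472 bp in the combined list. The combined list covered 1732 kb, or 1.73% of the genome spanned, against 821 kb in replicate 1 and 466 kb in replicate 2. The combined list also held 13 peaks narrower than 100 bp, down to 1 bp, while the narrowest replicate peaks measured 111 bp and 199 bp.

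The first comparison asked how far the replicates found the same binding regions. Nearly all of the strongest regions were found in both. All 100 of the strongest replicate 1 peaks overlapped a replicate 2 peak (95% interval 96.3% to 100%), and 99 of the strongest 100 replicate 2 peaks overlapped a replicate 1 peak. Of all replicate 2 peaks, 628 of 734 lay over a replicate 1 peak, or 85.6% (82.8% to 87.9%), against 1.88% with random placement. In the other direction the share was 622 of 1309, or 47.5% (44.8% to 50.2%), against 1.06% with random placement. Both permutation p-values were 0.000999, the smallest that the placements can give. The placements spread peaks evenly along each chromosome and ignore clustering and mappable sequence. The p-values therefore show only that the overlap exceeds that of evenly spread peaks. The lists differ in length, and with 734 top-ranked peaks from each the shares were 67.8% and 69.2%. The overlap was lower among weaker peaks. In replicate 1 it was 89.3% (85.5% to 92.2%) in the strongest 25% of peaks and 17.7% (14.0% to 22.2%) in the weakest 25%, and in replicate 2 it was 99.5% (97.0% to 99.9%) and 65.0% (57.9% to 71.6%).

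Regions that were strong in one replicate were also strong in the other. Across 628 overlapping pairs, −log10 q gave a Spearman correlation of 0.634 and a Pearson correlation of 0.882, each with a two-sided permutation p of 1e-05, the smallest that the resamples can give. Pearson's r was 0.820 without the 2 pairs farthest from the replicate 1 median, and peaks are not independent replicates. Replicate 1 had the larger −log10 q in 480 of the 628 pairs. The median −log10 q of these pairs was 8.13 in replicate 1 and 6.21 in replicate 2. Depth is unknown, so this difference cannot be read as a difference in binding.

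**Figure D1:**
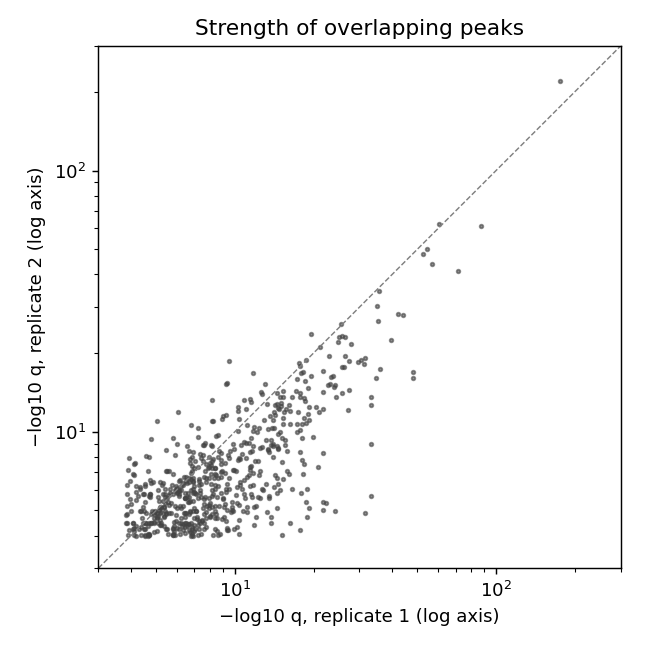
Each point is a pair of overlapping peaks, with −log10 q in replicate 1 on the x axis and in replicate 2 on the y axis, both on log axes, and the dashed line marks equal values. Most points lie below the line, 480 of 628, and the point at the upper right is the peak near the right end of chromosome I, at 176 and 220.

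The strongest regions of the combined list were broad and occurred on every chromosome. The first was a 12291 bp region at II 10541870 to 10554160 (WS180), with a −log10 q of 163 in the combined list. It corresponded to 4 peaks in replicate 1, with −log10 q up to 60.5, and to 2 peaks in replicate 2, up to 62.6. The region at X 16929302 to 16931959 reached 138 in the combined list, 87.3 in replicate 1 and 61.2 in replicate 2. A 9376 bp region at V 6220746 to 6230121 ranked 3 and was split into 3 peaks in replicate 1, with −log10 q up to 33.3, and 4 in replicate 2, up to 19.2. Further regions were III 8443365 to 8447508 with a −log10 q of 105, IV 17277814 to 17281961 with 103, V 14685089 to 14689108 with 99.9 and III 3866730 to 3869957 with 97.0. The leading region on chromosome I, at 7078931 to 7085285, ranked 10 with 84.5. Among the 20 strongest regions found in both replicates, 8 lay on chromosome III, 3 each on II, IV and X, 2 on V and 1 on I. Peaks at lin-13 and unc-119 were not identified, so these regions may include some that come from transgene copies. Their median width was 3451 bp against 472 bp in the whole list, and 16 of the 20 were 2000 bp or wider. Across the 2769 combined peaks, width and −log10 q had a Spearman correlation of 0.545. Width and q-value are not independent measures where reads are counted over a whole region. No fold enrichment was available, so this does not show that denser binding is broader. The genes at these regions were not analysed here, because no annotation of build WS180 was used.

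The combined list was then compared with the replicate lists. It took in nearly every replicate peak, 97.3% (96.3% to 98.1%) of replicate 1 and 98.8% (97.7% to 99.4%) of replicate 2, and added many weak regions that neither replicate list held. Of the 2769 combined peaks, 604 overlapped a peak in both replicates, or 21.8% (20.3% to 23.4%), against 0.845% with random placement (permutation p = 0.000999, one-sided). Another 635 were in replicate 1 only, 95 in replicate 2 only and 1435, or 51.8% (50.0% to 53.7%), in neither. The median −log10 q was 14.0 for peaks in both replicates and 4.67 for peaks in neither. With the combined list divided by q-value into 10 groups of nearly equal size, 92.8% (89.1% to 95.3%) of the strongest group were in both replicates, and 7.22% (4.72% to 10.9%) of the fifth. How the combined list was made is not given in the sources used here, and it was not treated as a measurement independent of the replicates. Since it held nearly every replicate peak, its overlap with both replicates was bound to exceed random placement. The permutation p of 0.000999 for that overlap is therefore no test of agreement.

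The strongest peak of both replicates was missing from the combined list. It lay near the right end of chromosome I, at 15063996 to 15067637 in replicate 1 with a −log10 q of 176 and at 15063993 to 15067640 in replicate 2 with 220. The next strongest peaks of these lists had 87.3 and 62.6. The last chromosome I peak of the combined list ended at 14790443. Of the other 34 replicate 1 peaks and 8 replicate 2 peaks absent from the combined list, the strongest had −log10 q of 6.33 and 4.95.

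The fourth question was how binding was spread over the chromosomes. Chromosome III held the most peaks for its length. Chromosomes I, V and X held fewer than their lengths give when peaks were counted one by one. They also had fewer peaks per 1 Mb bin than the other chromosomes, but did not pass the adjusted tests with bins as units. In the combined list, III held 691 peaks, or 25% (23.4% to 26.6%), against 13.8% of the length. This is 1.81 times its share of the length (1.70 to 1.93, exact binomial test, adjusted p = 1.87e-54). The ratio was 2.09 in replicate 1 and 2.02 in replicate 2. Chromosome III had 50.2 peaks per Mb, against 30.2 on II, 27.7 on IV, 21.6 on V, 21.3 on X and 20.4 on I. Chromosome V had 0.781 times its share (adjusted p = 3.04e-09, exact binomial test), with 0.740 and 0.797 in the replicates. The excess on III lowers the shares of all other chromosomes. Chromosome II, at 1.09 times, did not pass the adjusted threshold (adjusted p = 0.0502, exact binomial test), and IV was at 1.0 times its share (0.923 to 1.08). With 1 Mb bins as units, chromosome III had 50.7 ± 19 peaks per bin (SD, 13 bins) and the other chromosomes 24.0 ± 8.37 (84 bins), with a two-sided permutation p of 1e-05 (adjusted p = 7e-05). Chromosome I, at 20.5 ± 5.57 peaks per bin (15 bins), and V, at 21.2 ± 7.86 (20 bins), each had an adjusted permutation p of 0.0550. Their comparison bins include those of chromosome III. Without these, the others had 24.7 ± 8.71 peaks for I (69 bins, permutation p = 0.0753). For V they had 24.8 ± 8.41 (64 bins, permutation p = 0.0976), and neither chromosome passed the test.

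The X chromosome, which differs in dosage between hermaphrodites and males, held 375 combined peaks, or 13.5% (12.3% to 14.9%) against 17.6% of the length (exact binomial test, p = 6.85e-09, adjusted p = 1.03e-08). In 1 Mb bins it had 21.1 ± 5.81 peaks (SD, 17 bins) against 28.9 ± 14.6 (80 bins), with a permutation p of 0.0314 (adjusted p = 0.0550). The other bins include those of chromosome III. Without them the others had 24.7 ± 8.79 (67 bins), and X did not pass the test (permutation p = 0.111). The share was 14.0% in replicate 1 (p = 0.000428, adjusted p = 0.000642, exact binomial test). In replicate 2 it was 15.5% (13.1% to 18.3%), which did not pass the test (p = 0.146, adjusted p = 0.219, exact binomial test). Replicate 2 held 36 peaks on chromosome I, which was left out in a comparison added after the data were seen. Among the other 5 chromosomes X held 16.3% of replicate 2 peaks (13.8% to 19.3%) against 20.7% of their length (p = 0.00376, exact binomial test). These 5 include chromosome III, at 2.02 times its share of the whole length in replicate 2, and that excess lowers the share of X. Replicate 2 was not tested without both I and III, so this comparison cannot tell a deficit on X from the excess on III.

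**Figure D2:**
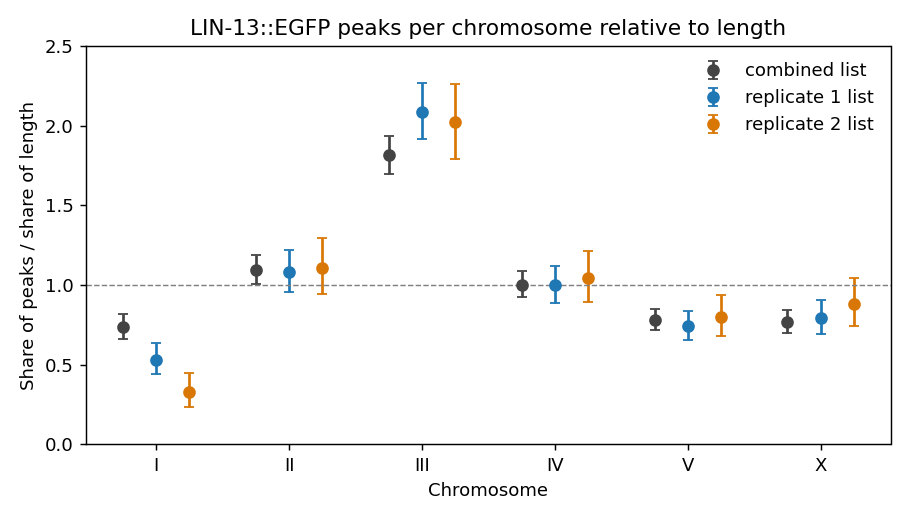
Share of a list's peaks on each chromosome divided by that chromosome's share of the length, with the combined, replicate 1 and replicate 2 lists as separate points, 95% Wilson intervals as bars and a dashed line at equal shares. Chromosome III lies at 1.81 to 2.09 in the 3 lists, and chromosome I falls from 0.736 in the combined list to 0.528 and 0.326 in the replicates.

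Chromosome I differed between the lists. It held 11.1% (9.97% to 12.3%) of combined peaks, 7.95% (6.60% to 9.54%) of replicate 1 peaks and 4.90% (3.56% to 6.72%) of replicate 2 peaks, against 15.1% of the length. Combined peaks on chromosome I were also found less often in the replicates than peaks of similar q-value elsewhere. In the second strongest of the 10 groups of the combined list, 25% (13.8% to 41.1%) of 36 chromosome I peaks were in replicate 2, against 74.7% (68.8% to 79.8%) of 241 peaks on the other chromosomes. Over all 10 groups the odds ratio of being found was 0.245 (0.164 to 0.367) in replicate 1 and 0.0804 (0.0436 to 0.148) in replicate 2, each with a one-sided permutation p of 1e-05, the smallest that the resamples can give. This comparison was chosen after the shortfall on chromosome I was seen, and the test was one-sided in that direction. The other 5 chromosomes had odds ratios from 1.0 to 1.49 in the 2 replicates. Each was compared with all remaining chromosomes, chromosome I included, which raises these ratios.

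**Figure D3:**
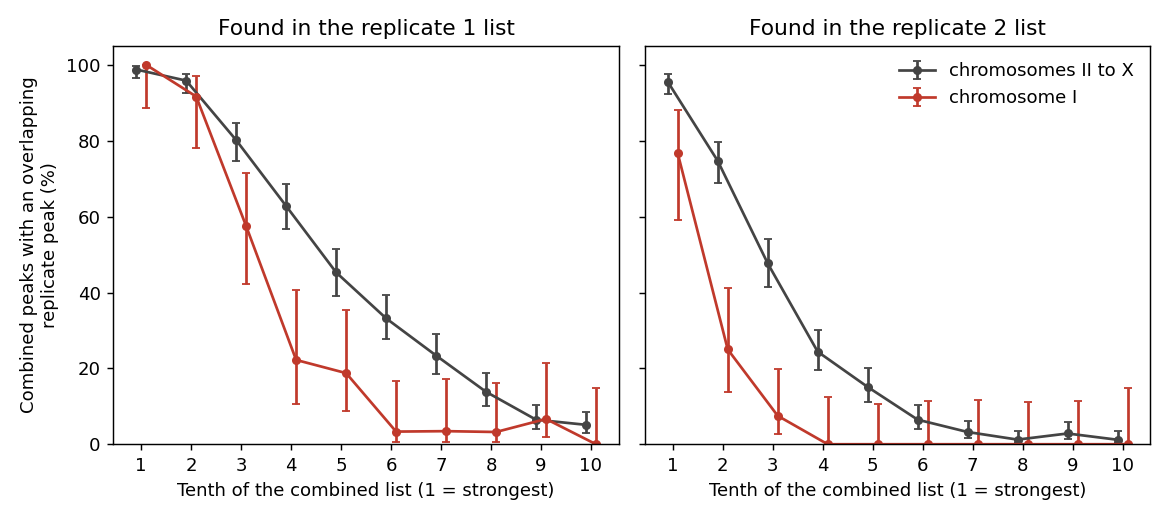
Percentage of combined-list peaks that overlap a peak of replicate 1 (left) or replicate 2 (right), in 10 groups of the combined list from strongest to weakest, for chromosome I and for chromosomes II to X, with 95% Wilson intervals. The chromosome I curve falls sooner, to 25% against 74.7% in the second strongest group for replicate 2.

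The last comparison set chromosome arms against centres, since C. elegans autosome arms are rich in repeats and centres in essential genes. Over all chromosomes no preference was seen. The arms held 1383 of 2769 combined peaks, or 49.9% (48.1% to 51.8%) against 50% of the length (exact binomial test, p = 0.970). The arm share was 50.6% in replicate 1 and 51.2% in replicate 2, with exact binomial p-values of 0.658 and 0.530. On chromosome V the arms held fewer peaks than the centre in all lists, with 41.2% (36.8% to 45.8%) of its combined peaks in the arms (exact binomial test, adjusted p = 0.00139). It had 38.1% in replicate 1 and 35.2% in replicate 2, with adjusted p-values of 0.00539 and 0.00857 by the exact binomial test. With 1 Mb bins as units, its arms had 16.6 ± 6.91 combined peaks per bin (SD, 9 bins) and its centre 25 ± 6.56 (11 bins), with an adjusted permutation p of 0.0778. The adjusted permutation p was 0.150 in replicate 1 and 0.0217 in replicate 2. Its left arm held 68 of 451 peaks and its right arm 118. On chromosome III the left arm held 218 peaks and the right arm 150, and the arm share of 53.3% (49.5% to 56.9%) did not pass the test (adjusted p = 0.282, exact binomial test). In replicate 2, chromosome II had 61.3% of its peaks in the arms (adjusted p = 0.0450, exact binomial test; adjusted p = 0.516 with bins as units, permutation test), against 52.9% in the combined list and 52.8% in replicate 1, and the difference between lists was not tested.

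**Figure D4:**
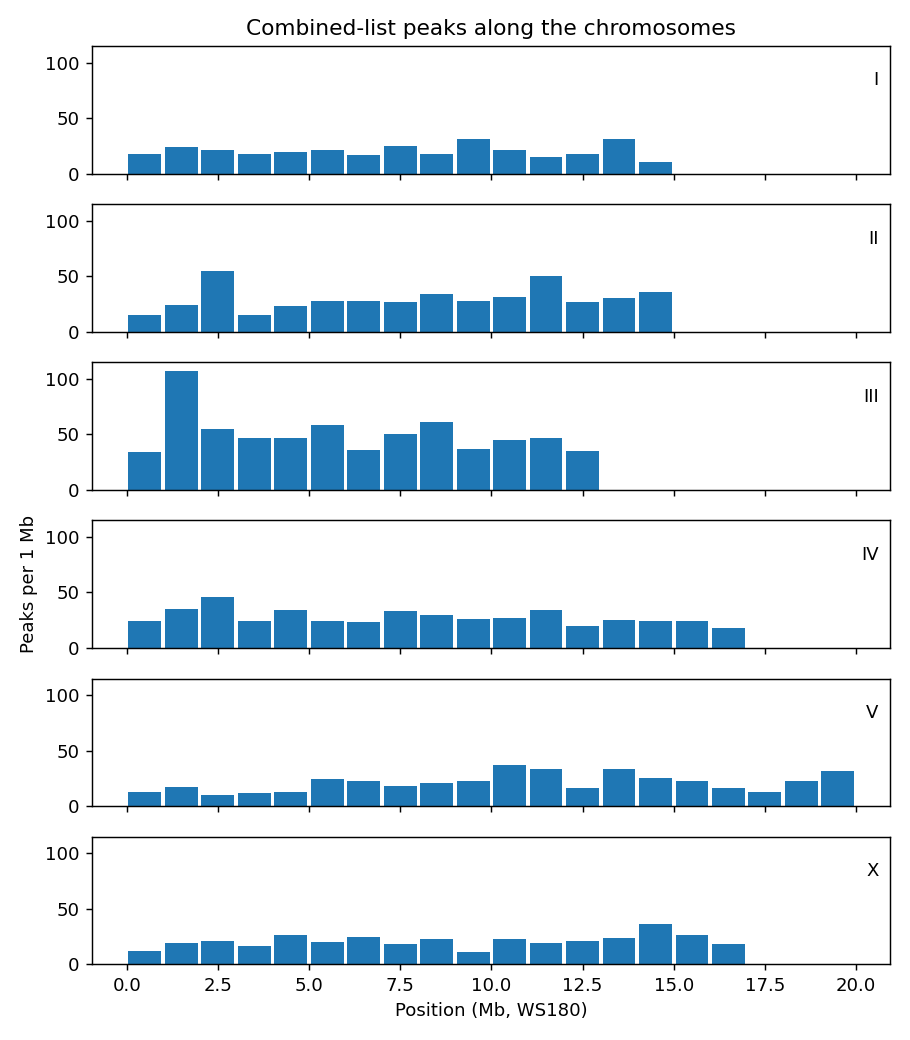
Combined-list peaks per full 1 Mb bin along each chromosome (x axis, position in Mb on WS180; y axis, number of peaks). The tallest bar, 107 peaks, is at 1 to 2 Mb of chromosome III, and the median bin holds 24.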

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

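The alternatives without chromosome I or III, those with 1 Mb bins and all those for chromosomes I and III were chosen after the data were seen. Of 48 alternatives over 8 results, 39 kept both the direction and the side of the 0.05 threshold, with p-values unadjusted. Every alternative for the overlap shares and the rank correlation was among these. For the chromosome shares, 9 of 9 held on III, 8 of 11 on X and 5 of 6 on I. For the arms, 1 of 6 held, because the main share of 49.9% lay so close to 50% that its side changed in the others. The absence of a preference that passes the test was kept in all 6. The overlap shares stayed far above random placement in every alternative run: 40.2% to 67.8% for replicate 1 in replicate 2, 69.2% to 86.6% in the other direction, and 16.6% to 23.2% for combined peaks in both replicates. Without chromosome I these were 48.8%, 85.0% and 23.2%. The last of these shares was bound to exceed random placement, because the combined list held nearly every replicate peak. The rank correlation was 0.69 with centres within 200 bp and 0.64 without chromosome I. The share on chromosome III ran from 24.7% to 31.2% and stayed above its share of the length in all 9 alternatives, and that on chromosome I stayed below in all 6 but did not pass the test with 1 Mb bins without chromosome III (15.3% of peaks in 17.9% of the bins). The share on X stayed below its share of the length in all 11 but did not pass the test for peaks in both replicates (15.6%) or with 1 Mb bins without chromosome III (17.8% of peaks in 20.2% of the bins), and the lists of single replicates gave 14.0% to 15.5%, with the upper value, from replicate 2, not passing. With peaks as units it passed without chromosome III (18.0% against 20.4% of the length; exact binomial test, p = 0.00705). Without chromosome I, X passed in replicate 2 (16.3% against 20.7% of the length) and among peaks in both replicates (exact binomial test, p = 0.0113). Chromosome III was kept in these 2 alternatives, and its excess of peaks lowers the share of X. Neither was run without both I and III, so they cannot tell a deficit on X from that excess. The share in arms was on the other side of 50% in the stronger 50% of the combined list (51.5%), in peaks found in both replicates (52.6%), without chromosome I (50.2%) and in the single replicates (50.6% to 51.2%). It was 47.6% with 1 Mb bins, 48.5% of which lay in arms. It passed the test in none of these 6 alternatives. No paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, have no values used here. All alternatives needing gene positions or sequence on build WS180, including gene 5′ ends as the background for chromosomes X and arms, were not run. Another strength column was not run either, as the q-value is the only one. Depth, being unknown, limits what a weak peak missing from 1 replicate shows.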

Other observations

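The odds ratio over all of chromosome I, the test of its q-values, both tests on chromosome III, the test on wide peaks and the placement of merged regions were chosen only after the results they bear on were seen. Binding regions lay close together at a few places. Chromosome III from 1 to 2 Mb held 107 combined peaks, 66 replicate 1 peaks and 32 replicate 2 peaks, against a median of 24 combined peaks per 1 Mb bin (quartiles 19 to 33). Its peaks were narrow, with a median of 327 bp against 472 bp in the whole list, and had a median −log10 q of 7.91 against 6.04. With peaks less than 5 kb apart taken as one cluster, the combined list formed 1805 clusters, of which 1231 were single peaks and 39 held 5 or more. The largest by number lay at III 1920887 to 1940410, with 13 peaks of which 8 were in both replicates. The next had 10 peaks at III 1610865 to 1625999 and 9 at II 2452458 to 2476065.

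Wide peaks were in both replicates more often than narrower ones. Of the 76 combined peaks of 2000 bp or more, 78.9% (68.5% to 86.6%) were in both replicates, against 20.2% (18.7% to 21.8%) of the narrower ones. The wide peaks were also stronger, with a median −log10 q of 32.4 against 5.87, and the shares were not compared at matched strength. Chromosome III held 11 of the 76, so that 1.59% of its peaks were wide against 3.13% elsewhere (Fisher's exact test, two-sided, p = 0.0315). The left end of chromosome I carried a peak in every list, at 3624 to 4216 in the combined list with a −log10 q of 17.9, and with 5.78 and 4.27 in the replicates. At the right end, the peak missing from the combined list was the last on the chromosome. In the WBcel235 gene table the last protein-coding gene of chromosome I, F31C3.6, is followed by the ribosomal RNA genes rrn-1.1, rrn-2.1, rrn-3.1 and rrn-1.2. The builds differ, so the peak was not assigned to a gene.

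Chromosome I peaks were fewer in the replicate lists than in the combined list. Weaker combined q-values on chromosome I do not account for this, since peaks of similar combined q-value were still found less often. The odds ratio was 0.0804 (0.0436 to 0.148) in replicate 2. Whether binding itself was weaker there cannot be told. Peaks were matched on the combined q-value only, and a scaling difference between the lists would shift that match. A local loss beside the strong peak at the right end is argued against by the left 50% of the chromosome, where the odds ratio was 0.0742 (0.0315 to 0.175) in replicate 2 and 0.220 (0.126 to 0.382) in replicate 1. In the strongest of 10 groups of the combined list, where replicate 1 held all 30 peaks on chromosome I and 244 of 247 elsewhere, the replicate 1 −log10 q was a median fraction of 0.430 of the combined one on I and 0.557 elsewhere, a difference of -0.127 (one-sided permutation p = 0.0002 within 5 strata of strength). This describes the pattern in other terms, and a chromosome-wide difference in scaling between the lists cannot be told apart by it from other causes, so that explanation stays open. No biological explanation was tested.

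Chromosome III held more peaks than its length gives. A more lenient threshold there would place the excess among weak peaks, but III held 30.3% (25.2% to 36.0%) of the strongest of 10 groups by q-value and 17.8% (13.7% to 22.7%) of the weakest. A single dense region does not account for it either: without the densest bin, at 1 to 2 Mb, III still had 46.0 ± 9.13 peaks per 1 Mb (SD, 12 bins) against 24.0 ± 8.37 elsewhere (permutation p = 1e-05, the smallest the resamples give). The lowest bin of III held 34 peaks, against a median of 23 per bin elsewhere. A higher density of LIN-13 sites on chromosome III and a scaling of chromosome III shared by all 3 lists stay open, and gene density was not examined. Peaks from the transgene copies of lin-13 and unc-119 were not set aside either, so their part in the counts on III is unknown.

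Combined peaks were clustered along the chromosomes. The variance to mean ratio of counts per 100 kb was 2.09 as a mean over the chromosomes, against 0.999 on average and 1.13 at most in 1000 random placements that kept the number of peaks on each chromosome. Broad regions split into several peaks may give part of this: with peaks less than 5 kb apart merged into 1805 regions, the ratio was 0.965, against 0.773 on average and 0.866 at most in 1000 placements of the same regions with gaps of at least 5 kb. Splitting at that scale therefore does not account for all of it, and the density of genes and of mappable sequence along the chromosomes stays open.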
